A study of Mus musculus with 12 samples.

How the data were processed

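RNA was sequenced from primary osteoblasts of neonatal mouse calvariae, the flat bones of the skull, from C57Bl/6J wild-type (WT) mice and mice labelled knockout (KO) for F2rl1, the gene of protease-activated receptor 2 (PAR2). Per the labels, cells were freed by collagenase digestion, precultured for 48 h and then kept for 4 days in a prostate-cell medium with 20% serum. This medium was either unconditioned or had been conditioned for 48 h by MDA-PCa-2b cells, a human prostate cancer line. The 12 samples fall into 4 groups of 3. RNA with an integrity number over 7.5 went into TruSeq libraries, which do not mark the strand. Per the submitters' processing notes, CASAVA 1.8.2, TopHat2 2.0.9 and Cuffdiff 2.1.1 were used with the mouse build GRCm38 (mm10).

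The values used are those of the authors' Cuffdiff table of fragments per gene and library. Its raw fragments are, per the file headers and their size, expected counts on an estimated count scale, and 94.3% of them are whole numbers. The FPKM column holds, per the file headers, fragment numbers divided by gene length and depth, which the authors scaled between libraries. It served only for 2 alternative fits. The authors' deposited test tables also hold p-values and q-values from Cuffdiff, of which only the counts of tests that the authors called significant are given. Other columns, such as the feature length in bases, are described per the file headers and gave positions and lengths. The tables come from 2 Cuffdiff runs with different gene numbers. Positions start 1 base later than in the authors' files, because 9604 gene starts there equalled an annotated start minus 1, and 886 equalled it.

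The table holds 25511 genes. Of these, 1714 have no symbol and took 2.69% to 3.10% of the fragments of a library, and 407 carry several symbols. Cuffdiff marked 50 entries as failed, and 2 genes exceeded its depth limit. Both kinds were kept with the values the table gives. Libraries held 15023994 to 16956754 fragments. Some genes known to be abundant have few fragments in this table, and the cause was not tested: Gapdh had 3 to 13 per library and Ppia 39 to 107, against 14965 to 30544 for Actb, 37190 to 66444 for Eef1a1 and 9387 to 11904 for Rplp0. Libraries 0 and 1 of the unconditioned WT group had the same total of 16309121 fragments and equal counts, to the last digit, for 91.8% of 17538 genes. Counting noise alone would make them differ more (chi-square 761 on 15476 degrees of freedom, against 94774.5 on 15127 for the next-closest pair), so they were used as 1 library and 11 libraries remained. A design with 12 libraries and 8 residual degrees of freedom had been written, and the fit has 7. The tables number libraries from 0 within a group, the sample titles from 1, and no source used here ties these numbers. One sample is titled WT and carries the KO genotype label. Its title places it in the unconditioned WT group, where it was kept. As 2 of the 3 libraries of that group are the same, it may be 1 of the 2 distinct libraries or be missing from them. This stays open.

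Rounded fragments were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr, quasi-likelihood with robust dispersion), in 1 fit of the 4 groups over 13603 genes. The 5 comparisons were KO against WT in each medium, conditioned against unconditioned medium in each genotype, and the interaction, the difference between the genotypes' medium effects. Adjusted p-values (Benjamini-Hochberg, over all genes of a comparison) under 0.05 count as called. Log2 changes carry a standard error (SE), taken as the size of the log2 change divided by the square root of the test's F value. Levels are CPM (counts scaled to library size) with their SD. The typical biological coefficient of variation was 0.238. No label says that the samples of a group are separate animals, so p-values measure the spread between these samples.

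There were 26 lists of genes: osteoblast differentiation and mineralised matrix, adipogenesis and lipid storage, cartilage, osteoclast-regulating factors of stromal cells, macrophage and leukocyte markers, osteoclast, endothelial, smooth muscle and myofibroblast, skeletal muscle, glial and meningeal, and keratinocyte markers, cell cycle, inflammatory cytokines and NF-kB targets, interferon-stimulated genes, Wnt targets and antagonists, BMP and TGF-beta targets, glycolysis and hypoxia response, integrated stress response and amino acid synthesis, ER chaperones, cholesterol synthesis, matrix proteases and inhibitors, PAR and coagulation proteins, the IGF axis, oxidative stress response, immediate early genes, and sex-linked genes. Each list was tested against all other genes with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the 26 lists, and again with the correlation estimated from the data. No list in any comparison had an adjusted p under 0.05 with the estimated correlation. The test called fry, which asks whether a list moves as a whole on balance and does not compare it with other genes, was run beside it.

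Genes to name followed a rule. F2rl1 and Il6 are always given. In each comparison of 2 groups, up to 10 called genes per direction with the largest log2 change were taken, with a mean log2 CPM of at least 1 and no overlap of the libraries. In the interaction, the 10 genes with the smallest p were taken. Each list gives up to 4 members, the 2 with the smallest p in each direction, and the surroundings of F2rl1 up to 5 called genes. The lists, this rule, the comparisons and most alternatives were fixed before the data were examined. Genes within 10 Mb of F2rl1 (5 and 20 Mb as alternatives) were compared with all others by Fisher's exact test.

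Alternatives were other scalings in edgeR (DESeq2 size factors, upper quartile), no filter, a filter at 1 CPM, unrounded counts, DESeq2 1.42.0, limma on log2 FPKM with 1 or 0.1 added, a fit of only the 2 groups compared, a block for the library number, and leaving out each library. After seeing the data 5 more were added: the repeated library counted as 2, a term for a batch of KO libraries 0 with WT libraries 2, the repeated library as number 1 in the block, both KO libraries 0 left out, and KO libraries 1 and 2 of conditioned medium left out. Whether a library number marks a pair was checked over 9827 genes by correlating departures from the group means. In KO each number paired across media (correlations 0.339, 0.31 and 0.318), although unconditioned library 2 correlated more with conditioned library 1 (0.393), so numbers 1 and 2 are not told apart. In WT the repeated library correlated with WT library 1 of the conditioned medium (0.466) but not with library 0 (-0.016), and library 2 with library 2 (0.498), which are not separate checks, since 2 libraries depart from their mean as mirror images. This makes fewer than the 3 pairs asked for, and equal numbers did not pair throughout across genotypes. KO library 0 correlated instead with WT library 2, at 0.36 in unconditioned and 0.449 in conditioned medium. KO libraries 1 and 2 correlated with the repeated WT library (0.338 and 0.306) and with conditioned WT library 1 (0.567 and 0.345). The block is therefore reported beside a result for the medium in KO, and as counts of calls for the medium in WT. In data simulated from this table with 200 changed genes per comparison, the fit recovered for KO against WT 26.5% of 2-fold and 81.6% of 4-fold changes in unconditioned medium, and 47% and 85.7% in conditioned medium. For the medium it recovered 33.3% and 79% in WT, and 46.5% and 82.5% in KO, with 13418 to 13443 genes run. Unchanged genes called numbered 10 for KO against WT in each medium, 9 for the medium in WT and 5 in KO. The simulated genes vary independently around 1 mean each, without differences that many genes of a library share. The shares recovered therefore do not give the power in the real libraries.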

Results

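RNA abundance was measured in mouse calvarial osteoblasts to ask what PAR2 contributes in medium conditioned by a prostate tumour line. PAR2 is a receptor that proteases activate by cleaving it. Libraries labelled WT and libraries labelled KO for F2rl1 were compared in unconditioned medium and in medium conditioned by MDA-PCa-2b cells, with 3 libraries in 3 groups and 2 distinct libraries in the unconditioned WT group. The unconditioned KO libraries 0 to 2 held 15885129, 15817823 and 16459099 fragments, and the conditioned KO libraries 16556983, 15610386 and 16956754. The distinct unconditioned WT libraries, 0 and 2, held 16309121 and 15023994 fragments, and the conditioned WT libraries 15488202, 15404676 and 15155753. The first principal component held 46.7% of the variance and placed the 5 unconditioned libraries between -37.2 and -30.8. Of the conditioned libraries, KO libraries 1 and 2 lay at 64.8 and 79.1, while KO library 0 lay at -4.81 and the WT libraries between -9.66 and 26.6.

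**Figure D1:**
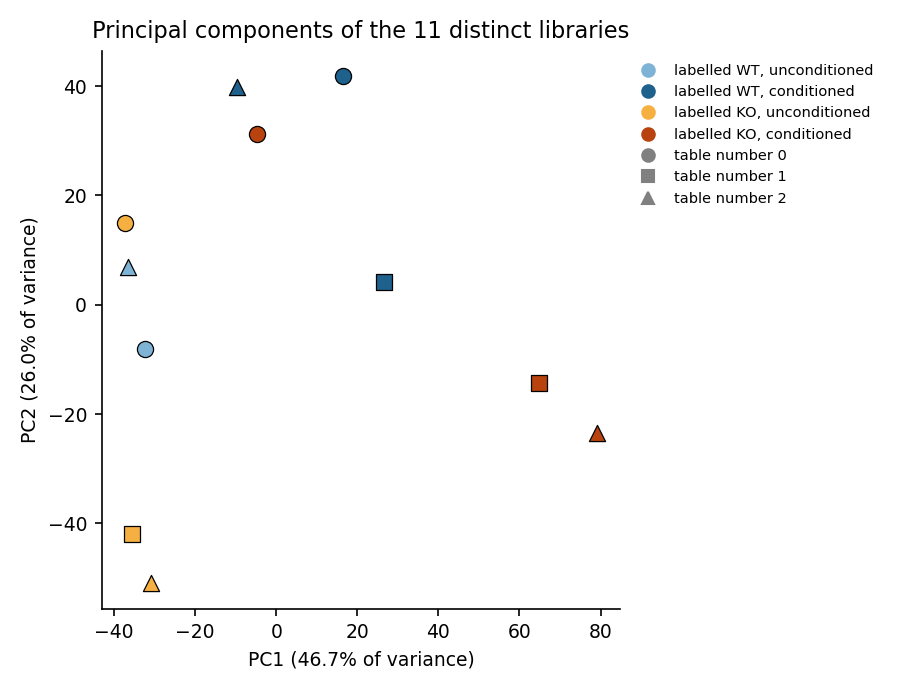
First and second principal component scores of log2 CPM (axes, with their share of the variance) of the 11 distinct libraries, coloured by group, with a marker for the library number. Conditioned KO libraries 1 and 2 lie at 64.8 and 79.1 on the first component and conditioned KO library 0 at -4.81.

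F2rl1 transcripts were scarce in every library and not lower in those labelled KO. The gene (XLOC_006189, chromosome 13, 95511730 to 95525240, GRCm38) had 33, 33 and 46 fragments in the unconditioned KO libraries and 31, 13 and 12 in the conditioned ones. It had 25 and 20 in the distinct unconditioned WT libraries and 14, 23 and 14 in the conditioned ones. Mean levels were 2.55 ± 0.476 CPM (SD, n = 3) in KO and 1.52 ± 0.173 CPM (n = 2) in WT in unconditioned medium, and 1.12 ± 0.702 and 1.13 ± 0.369 CPM (n = 3 each) in conditioned medium. The log2 differences between KO and WT were 0.74 (SE 0.48, adjusted p = 0.998) and -0.01 (SE 0.44, adjusted p = 0.989). The medium effect on F2rl1 was -0.43 (SE 0.48, adjusted p = 0.765) in WT and -1.19 (SE 0.43, adjusted p = 0.0765) in KO. Without conditioned KO library 0 the latter was called, at -1.82 (adjusted p = 0.00375). The table sums fragments over the whole gene and so cannot show which part of it was deleted. For this reason genotypes are given here as labelled. F2r, the gene of the related receptor PAR1, was abundant, with 2853 to 4701 fragments per library, while F2rl2 and F2rl3, the other two receptors of the family, had 0 to 5 fragments.

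**Figure D2:**
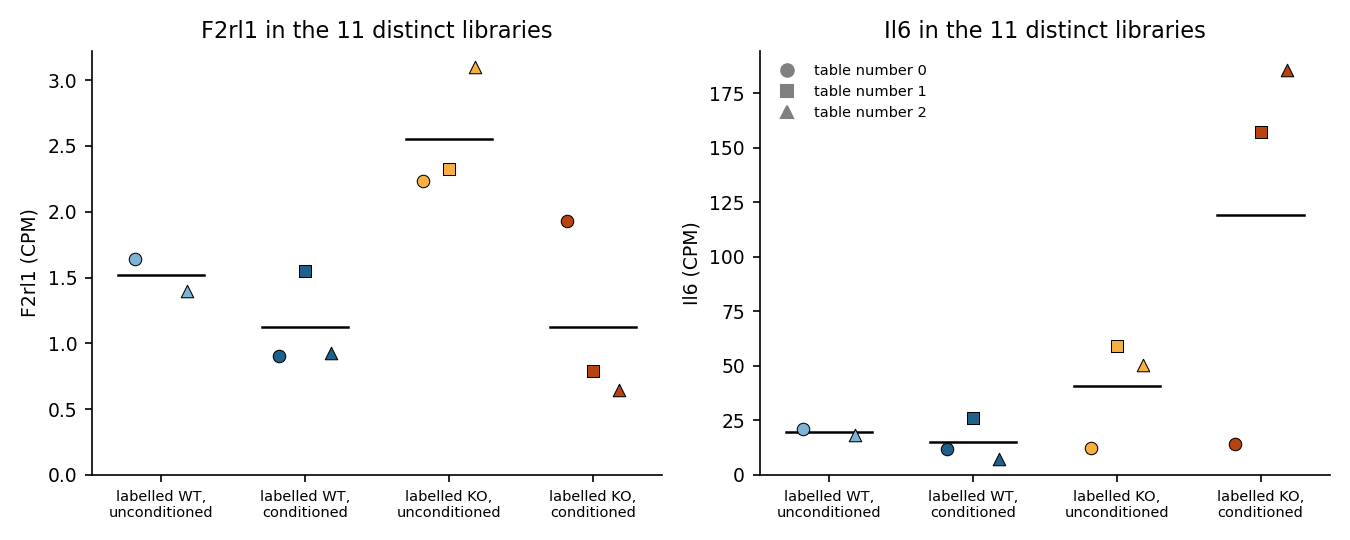
CPM of F2rl1 and of Il6 in each of the 11 distinct libraries by group, with the group mean as a horizontal line. F2rl1 averaged 2.55 CPM in unconditioned KO and 1.52 CPM in unconditioned WT libraries, and Il6 reached 119 CPM on average in conditioned KO libraries.

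In unconditioned medium the study's design asks what loss of the receptor changes without conditioning by tumour cells. The libraries labelled KO and WT differed there in 1 of 13603 genes. Pisd-ps3 (XLOC_024266), a pseudogene of the mitochondrial enzyme phosphatidylserine decarboxylase on an unplaced contig (51965 to 60879), was lower in KO, with 26.8 ± 2.30 CPM (SD, n = 3) against 59.1 ± 4.75 CPM (n = 2) and a log2 change of -1.14 (SE 0.12, adjusted p = 0.0355). Il6, an inflammatory cytokine that also acts on bone cells, had a log2 difference of 1.05 (SE 0.95, adjusted p = 0.998). Across all genes 294 had an unadjusted p under 0.05, against 680 that chance would give. Fewer than chance gives is a sign of a cautious test, so the single call does not show that the genotypes are alike.

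Of the 26 lists, 4 passed the list test in unconditioned medium, each without a called member over all genes or adjusted over the list alone. Genes of the integrated stress response and amino acid synthesis were higher in KO (median log2 0.48, adjusted p = 6.88e-07, 34 of 36 members positive), for example Pycr1, an enzyme of proline synthesis, at 0.80 (SE 0.46), and Vldlr at 0.56 (SE 0.29). On a centred log2 scale this list stood at 0.41 and 0.47 in KO libraries 1 and 2, but at -0.42 in KO library 0, level with WT libraries 0 and 2 (-0.28 and -0.42). Cell cycle genes were higher too (median 0.36, adjusted p = 2.83e-06, all 40 members positive), with Ccna2, a cyclin, at 0.77 (SE 0.47) and Pcna, the clamp of the replication fork, at 0.54 (SE 0.24). Skeletal muscle markers were lower (median -1.17, adjusted p = 5.14e-06, all 22 negative), with the acetylcholine receptor subunit Chrna1 at -1.21 (SE 0.47). Keratinocyte markers were lower as well (median -0.55, adjusted p = 0.0440, 1 of 9 positive), with Krt5 at -3.61 (SE 1.71). With an estimated correlation the adjusted p of all 4 was 0.867, and by fry it was 0.882. The osteoblast list (adjusted p = 0.759) and the adipogenesis list (0.107) were among the 22 lists not called. The median and the mean of the osteoblast, glial, interferon and PAR lists had opposite signs.

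Muscle and keratinocyte markers stood apart in 1 library. The median of the skeletal muscle list, on a centred log2 scale, was 1.99 in unconditioned WT library 0 and that of the keratinocyte list 1.31. Without this library the muscle list was no longer called and turned direction (adjusted p = 0.0701), as did the keratinocyte list (0.370), and the cell cycle list was not called (0.415). Without unconditioned KO library 0 the adjusted p was 0.0885 for muscle and 0.108 for keratinocyte markers, without KO library 1 it was 0.0941 for keratinocyte markers, and without KO library 2 the adipogenesis list was called (0.00104). The single call was lost without KO library 1, KO library 2, WT library 0 or WT library 2 (0 genes each), without KO library 0 there were 2 calls, and DESeq2 called 1 gene (354 at an unadjusted p under 0.05), limma 0. Without both KO libraries of number 0, 659 genes were called, 288 higher and 371 lower.

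The comparison in medium conditioned by tumour cells asks whether the genotype changes the cells there. No single gene passed the test between KO and WT in conditioned medium, while many gene lists leaned one way. Il6 (XLOC_016622, chromosome 5, 30013161 to 30019968) had 119 ± 91.7 CPM (SD, n = 3) in KO and 15.2 ± 9.84 CPM (n = 3) in WT, a log2 difference of 2.97 (SE 0.88, adjusted p = 0.357). Its fragments in KO were 231, 2584 and 3441, and in WT 184, 390 and 114. The edgeR fit called 0 of 13603 genes (1897 at an unadjusted p under 0.05, smallest adjusted p 0.249), DESeq2 2 and limma 0. Libraries of KO and WT did not overlap for 8.87% of genes, where chance gives 10%. Without conditioned KO library 0, 4507 genes were called, 2349 higher and 2158 lower, and Il6 was among them (log2 difference 3.50, adjusted p = 0.00462).

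Interferon-stimulated genes, which cells switch on against viruses, were higher in conditioned KO libraries (median log2 0.99, adjusted p = 4.42e-10, 31 of 34 positive). None was called over all genes and 6 were adjusted over the list alone. Examples are Rsad2 at 2.72 (SE 0.75) and Mx2 at 2.67 (SE 0.75), both antiviral effectors. On the centred scale the list stood at 0.29, 1.36 and 2.00 in KO libraries 0 to 2, and at 0.54, 0.86 and -0.36 in WT. Stress response genes were higher (median 0.50, adjusted p = 6.16e-05, 33 of 36 positive), with the stress-induced factor Atf3 at 4.10 (SE 1.05) and Ppp1r15a at 1.38 (SE 0.47). This list stood at -0.54, 0.57 and 0.79 in KO libraries 0 to 2 and at -0.47, 0.40 and -0.78 in WT, so that KO library 0 lay with the low WT libraries and WT library 1 near the high KO libraries. Cholesterol synthesis genes were lower (median -0.70, adjusted p = 3.98e-07, 2 of 25 positive), with Nsdhl, an enzyme of a late step, at -1.01 (SE 0.32). This list stood at -0.14, 0.01 and -0.26 in KO and at 0.48, 1.001 and -0.36 in WT, so that WT library 2 lay below every KO library. Genes of glycolysis and the hypoxia response (median -0.45, adjusted p = 6.36e-05, 5 of 39 positive) and of the oxidative stress response (median -0.57, adjusted p = 0.000140, 4 of 28 positive) were lower, with Higd1a at -0.80 (SE 0.39) and Gstm1 at -0.88 (SE 0.32). Also lower were targets of BMP and TGF-beta (median -0.37, adjusted p = 0.000232), with the BMP antagonist Grem1 at -1.28 (SE 0.46), and cartilage genes (median -0.75, adjusted p = 0.000245), with the cartilage proteoglycan Acan at -1.40 (SE 0.39). Smooth muscle genes (median -0.48, adjusted p = 0.00645) and macrophage markers (median -0.48, adjusted p = 0.00876) were lower, with Pdgfrb at -0.44 and Cybb at -1.05. Cell cycle genes passed as higher (adjusted p = 0.0476, mean 0.16), although their median was -0.01 and 19 of 40 were positive. Several of the lower lists were not low in KO library 0. KO libraries 0 to 2 stood at 0.21, -0.67 and -0.92 for glycolysis (WT 0.15, -0.45 and 0.38) and at 0.17, -0.36 and -0.57 for oxidative stress (WT 0.36, -0.19 and 0.44). They stood at 0.32, -0.64 and -0.99 for BMP and TGF-beta targets (WT 0.06, 0.00 and 0.19), at 0.30, -1.09 and -1.40 for smooth muscle (WT -0.63, -0.00 and 0.17), at -0.04, -0.65 and -0.64 for cartilage (WT 0.61, 0.03 and -0.15), and at 0.64, -0.14 and -0.81 for macrophage markers (WT 0.31, 0.00 and 0.73).

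Apart from the interferon list, no list called in conditioned medium had a called member, over all genes or over the list alone. With an estimated correlation the adjusted p was 0.727 for 7 of these 10 lists, the interferon list among them, 0.735 for the stress response and macrophage lists, and 0.833 for the cell cycle. By fry the 10 lists had adjusted p-values of 0.441 to 0.739. The cell cycle call was lost without conditioned KO library 0 (adjusted p = 0.293), without WT library 1 (0.433) and without WT library 0 (0.545, reversed). Without WT library 1 the cholesterol list (0.0501) and the smooth muscle list (0.0641) were not called, and the macrophage list was not called without KO library 2 (0.170) or WT library 2 (0.0896). The adipogenesis list, at 0.0531 with all libraries, was called without KO library 1 (0.0212), KO library 2 (0.00167), WT library 0 (0.0384) or WT library 2 (0.00449). The osteoblast list was not called (0.429), nor were the keratinocyte (0.0649) and PAR lists (0.0593).

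In WT cells the conditioned medium raised genes such as Gpnmb and Rragd about 8- to 9-fold and lowered Serpina3n and Fkbp5. By camera at the preset correlation, genes of the cell cycle were lower and those of the interferon response and of osteoclasts higher as groups. With the estimated correlation none of these lists was called. Of 13603 genes, 242 were called, 167 higher and 75 lower, and 155 by more than 2-fold. Gpnmb (XLOC_018181, chromosome 6, 49036518 to 49070856), a membrane glycoprotein of osteoblasts, osteoclasts and macrophages, rose from 97.2 ± 2.78 CPM (SD, n = 2) to 795 ± 149 CPM (n = 3), a log2 change of 3.03 (SE 0.41, adjusted p = 0.0139). Rragd (chromosome 4, 32982998 to 33022180), a GTPase that signals amino acid supply at the lysosome, rose from 3.29 ± 1.29 to 30.03 ± 8.52 CPM, by 3.18 (SE 0.63, adjusted p = 0.0417). Serpina3n (chromosome 12, 104406708 to 104414329), a secreted inhibitor of serine proteases, fell from 408 ± 15.1 to 38.4 ± 15.7 CPM, a log2 change of -3.41 (SE 0.64, adjusted p = 0.0335). Fkbp5 (chromosome 17, 28398753 to 28517508), a cochaperone of the glucocorticoid receptor, had a log2 change of -2.73 (SE 0.38, adjusted p = 0.0139). Angptl4, an inhibitor of lipoprotein lipase, fell from 71.1 ± 1.33 to 11.8 ± 4.51 CPM. The other genes with the largest rises were Gng4 (3.13), Slc4a10 (3.05), Atp6v0d2 (2.71), Cd200r4 (2.70), Adh1 (2.64), Tnxb (2.56), Uap1l1 (2.56) and Fam180a (2.42). The other largest falls were in Serpina3m (-5.29), Rnf180 (-2.70), Ankrd55 (-2.63), Spc24 (-2.49), Clca1 and Clca4 read as 1 gene (-2.37), Gldc (-2.34) and Il31ra (-2.26). Il6 stayed within its error in WT, at -0.37 (SE 0.93, adjusted p = 0.917).

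Among the lists in WT, cell cycle genes were lower as a group (median log2 -1.70, adjusted p = 7.53e-36). Of 40 members 4 fell, or 33 adjusted over the list alone, among them Prc1, which organises the spindle midzone, at -1.90 (SE 0.39, adjusted p = 0.0458), and the cyclin Ccne1 at -0.97 (SE 0.20). With an estimated correlation the adjusted p was 0.284. Interferon-stimulated genes were higher (median 1.26, adjusted p = 1.72e-13, all 34 positive), with 0 called over all genes and 13 over the list alone. Irf7, the regulator of interferon production, was at 1.67 (SE 0.39, adjusted p = 0.0602), and the list had an adjusted p of 0.505 with an estimated correlation. The osteoclast list was higher (median 0.63, adjusted p = 5.45e-06), with 3 of 9 called, 4 over the list alone, and an adjusted p of 0.138 with an estimated correlation. Its leading members were Atp6v0d2, a proton pump subunit, at 2.71 (SE 0.31) and Ctsk, the collagen-degrading protease cathepsin K, at 1.46 (SE 0.28, adjusted p = 0.0373). Nfatc1, the master regulator of osteoclast formation, was at -0.08 (adjusted p = 0.941).

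Cholesterol synthesis genes were higher in WT (median 0.53, adjusted p = 0.00121, all 25 positive), with none called and Insig1 at 1.17 (SE 0.47). On the centred scale conditioned WT libraries 0 and 1 stood at 0.48 and 1.001, but library 2 at -0.36, below both unconditioned libraries (-0.16 and -0.01). Oxidative stress genes were higher (median 0.25, adjusted p = 0.0215), and 2 of 28 rose, in both counts: the iron store Ftl1 by 1.37 (SE 0.25) and the cystine carrier Slc7a11 by 1.31 (SE 0.27). Inflammatory genes were lower (median -0.16, adjusted p = 0.0231). The neutrophil attractant Cxcl5 fell by 1.48 (SE 0.20), as 1 of 25 or 2 over the list alone, and the list had an adjusted p of 0.284 with an estimated correlation. Smooth muscle genes were lower as a group (median -0.64, adjusted p = 0.0391), yet their only called member of 18, the pericyte proteoglycan Cspg4, rose by 1.33 (SE 0.16), and over the list alone 1 rose and 1 fell. Skeletal muscle markers (median -0.60, adjusted p = 0.0391, 0 of 22 called) included Ckm at -1.99 (SE 1.04). Genes of glycolysis and hypoxia were lower (median -0.22, adjusted p = 0.0394), while the 1 called member of 39 in both counts, the enolase Eno2, rose by 1.18 (SE 0.23). Immediate early genes were lower (median -0.35, adjusted p = 0.0394, 0 of 28 called), with Egr2 at -1.96. With an estimated correlation the adjusted p was 0.851 for the cholesterol, oxidative stress, smooth muscle, skeletal muscle, glycolysis and immediate early lists. By fry the cell cycle and inflammatory lists (adjusted p = 0.0406 each) and the osteoclast list (0.00893) were called, as was the endothelial list as higher (0.0406), while the interferon list (0.206) and these 6 (0.564 to 0.666) were not.

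The lists closest to the study's question were not called in WT. Of the osteoblast list (adjusted p = 0.110, median -0.19) 0 of 27 members changed, and of the adipogenesis list (0.0926) 1 of 25 rose: Apoe, a lipid carrier, by 1.56 (SE 0.33), with 1 higher and 1 lower over the list alone. Of the factors by which stromal cells regulate osteoclasts (0.810) 0 of 15 changed, with the osteoclast-inducing Tnfsf11 at -1.78 (adjusted p = 0.102). For matrix proteases (0.0817) 1 of 25 rose over all genes, against 3 higher and 2 lower over the list alone, and Mmp10 was at 6.59 (SE 1.36, adjusted p = 0.0508). The stress response list (0.368) had 1 of 36 called, Slc7a11, and the IGF list (0.927) 1 of 15, Igf2r, which rose by 0.81. No member was called over all genes in the cartilage (0.864), macrophage (0.134), endothelial (0.138), glial (0.426), keratinocyte (0.810), Wnt (0.864), BMP and TGF-beta (0.927), ER chaperone (0.134), PAR (0.210) and sex-linked lists (0.951). Over the list alone the cartilage, macrophage, endothelial, Wnt and BMP lists had 1 call each. In the cartilage and BMP lists the median and the mean had opposite signs. Xist, which is expressed from an inactive X chromosome, had 307 to 907 CPM, and the Y-linked Ddx3y 34.1 to 93.0 CPM, so every library held RNA of both sexes.

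The count in WT rested on single libraries. Without unconditioned library 0 there was 1 call and without library 2 there were 0; without conditioned libraries 0, 1 and 2 there were 15, 79 and 444. With a replicate block the edgeR fit called 155 genes, 70 higher and 85 lower, of which 71 were among the 242, and with the repeated library as number 1 it called 0 (1729 at an unadjusted p under 0.05). With unconditioned library 0 left out the calls of the oxidative stress (0.0600), smooth muscle (0.0600), glycolysis (0.0740) and skeletal muscle lists (0.151, reversed) were lost, and without unconditioned library 2 that of the immediate early genes (0.696). Without conditioned library 0 the oxidative stress (0.0744), smooth muscle (0.123), skeletal muscle (0.302) and immediate early lists (0.0744) were not called. Without conditioned library 1 this held for cholesterol (0.357), inflammatory (0.0761), glycolysis (0.666) and immediate early genes (0.498). Without conditioned library 2 it held for oxidative stress (0.155) and skeletal muscle (0.487), and the adipogenesis list was called (0.0211). Skeletal muscle markers were high in unconditioned library 0 (1.99) and conditioned library 1 (1.74) and lay between -1.40 and 0.32 in the other 9 libraries.

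In the libraries labelled KO the same medium raised interferon-stimulated genes many-fold. Genes of cell division, smooth muscle and glycolysis were lower as groups by camera at the preset correlation, but not with the estimated one. Of 13603 genes, 2484 were called, 1317 higher and 1167 lower, and 1108 by more than 2-fold. Isg15, a ubiquitin-like protein of the interferon response, rose from 6.25 ± 1.45 to 195 ± 147 CPM (SD, n = 3 each), a log2 change of 4.96 (SE 0.81, adjusted p = 0.00795). Ifit1, which binds viral RNA, rose from 7.92 ± 0.346 CPM by 5.14 (SE 0.85, adjusted p = 0.00795). Ppargc1a, a coactivator of mitochondrial genes, rose by 4.66 (SE 0.65, adjusted p = 0.00497), and Rragd by 4.23 (SE 0.56, adjusted p = 0.00463). Serpina3n fell from 596 ± 272 to 32.3 ± 25.8 CPM, a log2 change of -4.21 (SE 0.63, adjusted p = 0.00638). Avpr1a, a vasopressin receptor, had a change of -4.32 (SE 0.72, adjusted p = 0.00820), and the neuropeptide gene Npy one of -4.21 (SE 0.79, adjusted p = 0.0111). The other largest rises were in Atf3 (5.29), Rsad2 (4.83), Iyd (4.82), Mx1 (4.38), Mx2 (4.32) and Ajap1 (4.19). The other largest falls were in Serpina3m (-6.90), Tnn (-3.88), Apln (-3.82), Ctla2a (-3.75), Il1rn (-3.64), Galnt16 (-3.35) and Hspb7 (-3.24). With a block for the library number, Iyd (adjusted p = 0.0509) and Apln (0.0530) missed the threshold when the repeated WT library was taken as number 1. Il6 was at 1.55 (SE 0.83, adjusted p = 0.199), and without conditioned KO library 0 it was called at 2.08 (adjusted p = 0.0220).

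Of 34 interferon-stimulated genes 31 rose in KO, or 32 adjusted over the list alone (median log2 2.48, adjusted p = 4.13e-20), among them Irf7 by 2.15 (SE 0.34) and Ifit3, read as 1 gene with I830012O16Rik, by 4.53 (SE 0.71). Of 40 cell cycle genes 28 fell, or 34 over the list alone (median -2.01, adjusted p = 2.51e-22), among them Ccna2, with -2.85 (SE 0.45), and Racgap1, with -1.86 (SE 0.30), while the replication genes Mcm2 and Tyms stood at 0.25 and 0.10. Both lists had an adjusted p of 0.538 with an estimated correlation. In glycolysis and hypoxia (median -0.76, adjusted p = 9.52e-07) 9 of 39 fell and 1 rose, or 16 and 1 over the list alone. The collagen-modifying P4ha2 fell by 1.41 (SE 0.24), the glucose carrier Slc2a1 fell by 0.85 (SE 0.15), and Eno2 rose by 1.43 (SE 0.21). Of 18 smooth muscle genes 6 fell and 1 rose, or 11 and 1 over the list alone (median -1.42, adjusted p = 0.000179), with Rgs5 at -2.25 (SE 0.47) and Cspg4 at 1.19 (SE 0.14). On the centred scale conditioned KO libraries 0 to 2 stood at 0.30, -1.09 and -1.40 for this list and at 0.21, -0.67 and -0.92 for glycolysis and hypoxia. Of 21 ER chaperones 4 fell, or 5 over the list alone (median -0.36, adjusted p = 0.00159), such as the disulfide isomerase Pdia6, which fell by 0.98 (SE 0.19). Of 18 PAR and coagulation genes 1 fell in both counts (median -0.49, adjusted p = 0.0225): F3, tissue factor, the starter of coagulation, with -1.22 (SE 0.28, adjusted p = 0.0200, or 0.0577 and 0.0602 with the replicate block). For this list conditioned KO libraries 0 to 2 stood at 0.12, -0.62 and -0.78. These last 4 lists had an adjusted p of 0.619 with an estimated correlation. By fry the glycolysis (adjusted p = 0.0794), ER chaperone (0.0679) and PAR lists (0.0794) were not called, while the interferon and cell cycle lists (0.0294 each), the smooth muscle list (0.0298) and the osteoclast list (0.00945) were. Of 9 osteoclast genes 4 rose in both counts (median 0.36, adjusted p = 0.00431, and adjusted p = 0.538 with an estimated correlation), among them Atp6v0d2 by 1.70 (SE 0.25) and Clcn7, a chloride carrier of lysosomes, by 1.60 (SE 0.22).

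The osteoblast and adipogenesis lists were not called by camera in KO either, and their members moved in both directions. Of 27 osteoblast genes 7 fell and 1 rose, or 8 and 2 over the list alone (median -0.52, adjusted p = 0.0747), and fry called the list as lower (adjusted p = 0.0298). Bglap2, an osteocalcin gene and a marker of mature osteoblasts, rose by 3.21 (SE 0.90, adjusted p = 0.0367, or 0.0652 and 0.0676 with the replicate block). Enpp1, which makes the mineralisation inhibitor pyrophosphate, had a change of -1.73 (SE 0.34), and Fkbp10, a collagen chaperone, one of -0.62 (SE 0.14). Pdpn, an early osteocyte marker, was at 0.75 (adjusted p = 0.0571) and was called with the block (0.0373 and 0.0389). Bglap2 was at 4.98 without unconditioned KO library 0 and lost its call without unconditioned library 1 (adjusted p = 0.118), unconditioned library 2 (0.126), conditioned library 1 (0.144) or conditioned library 2 (0.0605). Fkbp10 lost it in the same 4 fits (0.0662 to 0.0805), and Enpp1 without unconditioned library 1 (0.0561) or conditioned library 1 (0.0583). Of 25 adipogenesis genes 2 rose and 2 fell, or 6 and 2 over the list alone (adjusted p = 0.463): Apoe rose by 2.28 (SE 0.30) and the fatty acid carrier Cd36 by 1.24 (SE 0.32), while Fabp4 fell by 2.88 (SE 0.52) and Cebpd, an early adipogenic factor, fell by 1.14 (SE 0.26). Cebpd lost its call in the 4 fits named for Bglap2 (0.0649 to 0.0920), Cd36 in all of these but the one without conditioned library 2 (0.0994 to 0.108), and Fabp4 without conditioned library 1 (0.0542).

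The remaining lists were not called in KO. Inflammatory genes (adjusted p = 0.340) had 2 risen and 5 fallen members of 25, or 3 and 6 over the list alone, with Cxcl9, which interferon induces, at 5.77 (SE 1.41) and Il1rn at -3.64 (SE 0.70). BMP and TGF-beta targets (0.199) had 3 in each direction of 33, or 3 and 6 over the list alone, with the Notch target Hey1 at 3.75 (SE 0.74) and Ltbp2 at -1.46 (SE 0.35). Wnt targets and antagonists (0.463) had 1 risen and 3 fallen of 23 in both counts, with the antagonists Frzb at 0.90 (SE 0.19) and Sfrp1 at -3.04 (SE 0.82). Matrix proteases (0.830) had 3 risen and 5 fallen of 25, or 6 and 5 over the list alone, with Mmp14 at 0.91 (SE 0.20) and Adamts12 at -2.34 (SE 0.41). Stress response genes (0.442) had 4 risen and 1 fallen of 36 in both counts, with the stress cytokine Gdf15 at 0.95 (SE 0.15) and Pck2 at -1.54 (SE 0.45). The IGF axis (0.463) had 2 in each direction of 15, or 2 and 3 over the list alone, with Igfbp5 at 2.38 (SE 0.48) and Stc1 at -1.30 (SE 0.22). Stromal osteoclast factors (0.684) had 1 in each direction of 15 in both counts, with Ccl2 at 0.89 (SE 0.25) and Tnfsf11 at -1.98 (SE 0.46). In the cartilage list (0.103) the transcription factor Sox6 rose by 0.69 (SE 0.12) and the collagen Col11a1 fell by 1.72 (SE 0.26), of 17 and in both counts. Endothelial markers (0.339) had 3 risen of 9 in both counts, with Tek at 1.27 (SE 0.36) and Vwf at 1.54 (SE 0.44), and fry called the list as higher (adjusted p = 0.0178).

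Among the last lists in KO, oxidative stress genes (adjusted p = 0.361) had 1 risen and 2 fallen of 28, against 1 and 0 over the list alone, with Ftl1 at 1.19 (SE 0.22) and Gsr at -1.03 (SE 0.28). Immediate early genes (0.716) had 2 risen and 1 fallen of 28, against 1 and 0, with Nr4a3 at 3.45 (SE 0.74). A single gene rose in the macrophage list (0.716; Cybb, 2.63, SE 0.78, of 20), in the glial list (0.572; Ptgds, 5.15, SE 1.56, of 12) and in the cholesterol list (0.830; Tm7sf2 and Vps51 read as 1 gene, 0.43, of 25), and 0 did so over the list alone. In the skeletal muscle (0.716), keratinocyte (0.716) and sex-linked lists (0.747) 0 members were called.

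The count in KO also moved with single libraries, in both directions. Without conditioned KO library 0 it was 6094, and without libraries 1 and 2 it was 319 and 687; without unconditioned KO libraries 1 and 2 it was 400 and 457. Without both KO libraries of number 0 it was 6822, without conditioned KO libraries 1 and 2 it was 2, and in a fit of these 2 groups alone it was 534. Of the genes with the largest changes, Atf3 lost its call without unconditioned library 1 (adjusted p = 0.0753), unconditioned library 2 (0.0683), conditioned library 1 (0.0562) or conditioned library 2 (0.0505). Iyd (0.0507 to 0.0743) and Mx1 (0.0620 to 0.0897) lost it in the same 4 fits, and Tnn without any library but conditioned library 0 (0.0870 to 0.149). Mx2 lost it without unconditioned library 1 (0.0625), unconditioned library 2 (0.0532) or conditioned library 1 (0.0521), and Apln without the same libraries (0.0542, 0.0504 and 0.0637). Rsad2 lost it without unconditioned library 2 (0.0508), and Npy (0.0562), Il1rn (0.0570) and Hspb7 (0.0521) without conditioned library 1. Of the list members, F3 lost its call in the same 4 fits as Atf3 (0.0775 to 0.0890), Rgs5 without unconditioned libraries 1 or 2 or conditioned library 1 (0.0518 to 0.0738), Pdia6 without unconditioned library 1 (0.0551) or conditioned library 1 (0.0572), and Slc2a1 without conditioned library 1 (0.0558). The PAR list was not called without unconditioned library 0 (0.109) or conditioned library 2 (0.0839), and the osteoblast list was called as lower without conditioned library 0 (0.0305) or conditioned library 1 (0.0400).

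**Figure D3:**
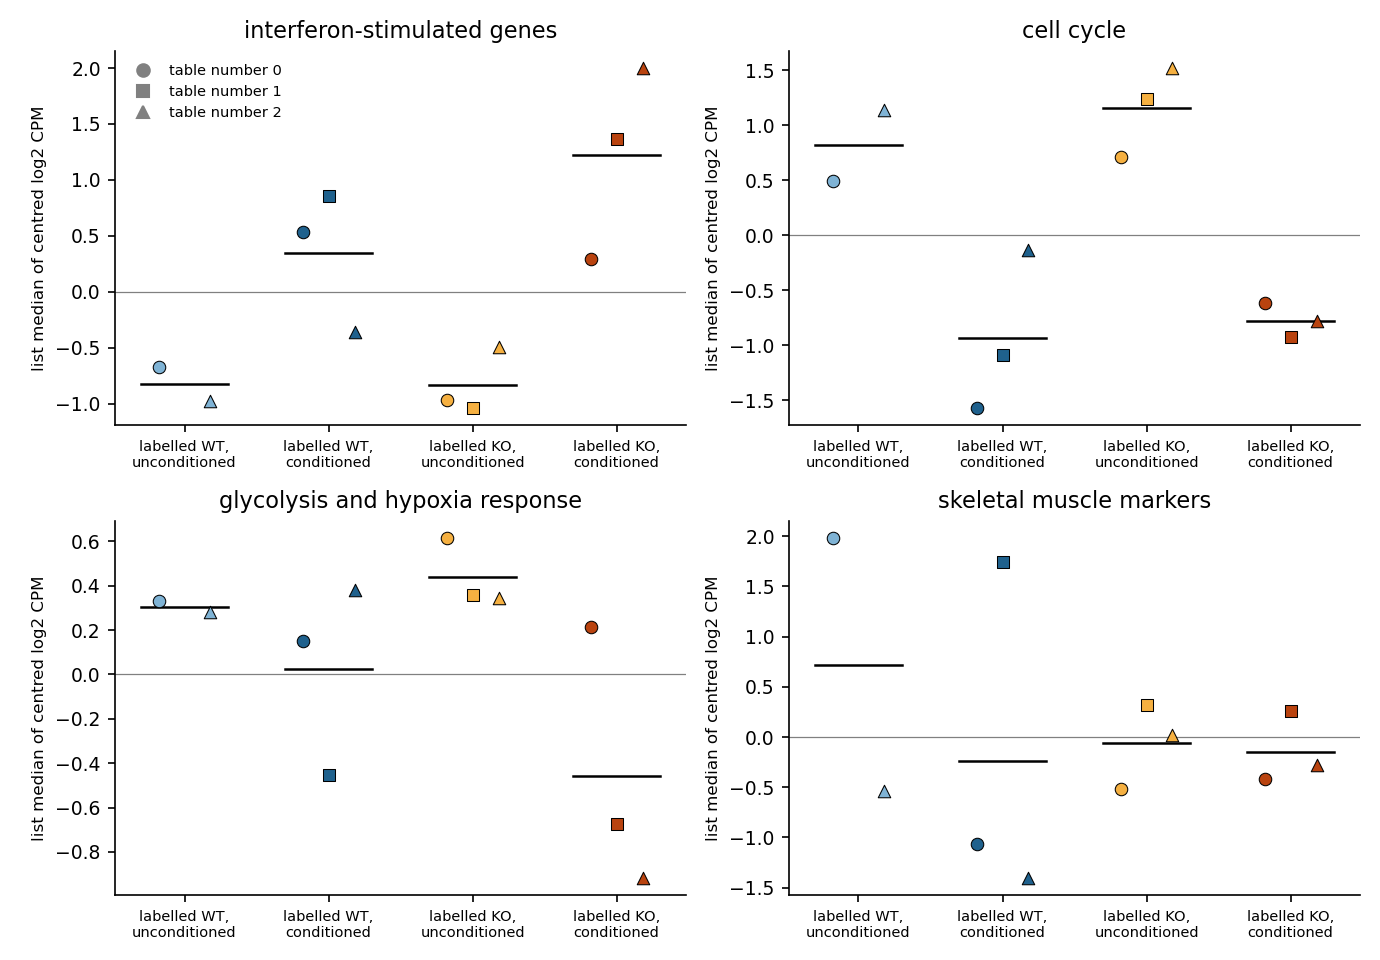
Median centred log2 CPM of 4 gene lists (interferon-stimulated genes, cell cycle, glycolysis and hypoxia, skeletal muscle markers) in each of the 11 distinct libraries by group, with markers for the library number and a horizontal line at the group mean. Interferon genes stood at 0.29, 1.36 and 2.00 in the conditioned KO libraries, and muscle markers at 1.99 in unconditioned WT library 0 and 1.74 in conditioned WT library 1.

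The medium acted on WT and KO cells in largely the same direction. Across 13603 genes, which are not independent replicates, the log2 changes in WT and KO correlated with a Pearson r of 0.73 and a Spearman rho of 0.65. These 2 comparisons share no library, but their calls share the estimate of each gene's spread. The chance numbers and exact tests that follow take the calls as independent. Of the called genes, 161 rose in both, against 16.2 by chance (Fisher's exact test, two-sided, p = 8.44e-158), and 72 fell in both, against 6.43 (p = 1.09e-73). Rragd and Atp6v0d2 rose and Serpina3n and Serpina3m fell in both, and 0 genes were called in opposite directions. Of the 2484 genes called in KO, 97.4% had the same sign in WT, where their median size was 0.51 against 0.92 in KO. Of the 242 called in WT, 241 had the same sign in KO, with median sizes of 1.22 and 1.19.

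**Figure D4:**
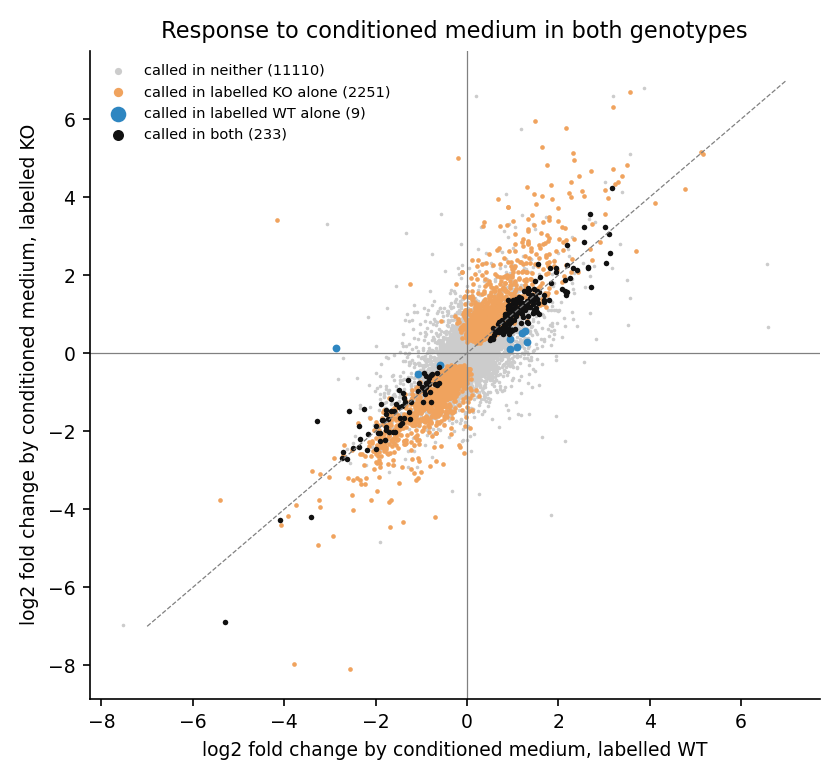
Log2 change by conditioned medium in WT (horizontal axis) and in KO (vertical axis) for 13603 genes, coloured by where they were called. A total of 233 genes were called in both, 2251 in KO alone and 9 in WT alone, and none of the 233 changed in opposite directions.

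Whether the genotype changed the answer to the medium is tested by the interaction. It called 0 of 13603 genes in edgeR, 0 in DESeq2 (501 at an unadjusted p under 0.05) and 0 in limma. In edgeR 412 genes had an unadjusted p under 0.05, against 680 that chance would give, and the smallest adjusted p was 0.819. So low a number is a sign of a cautious test, and 0 calls do not show that the genotypes answered alike. Il6 had an interaction of 1.92 (SE 1.23) and F2rl1 of -0.76 (SE 0.65). The 10 genes with the smallest p, all with an adjusted p of 0.819, were Mrpl2 (-0.68), Hspa12a (-1.0045), Mthfd1l (-0.75), Med12l (0.89), Tmem256 (-0.83), Angptl4 (1.12), Wdr53 (1.01), Hmgn5 (2.14), Mttp (0.62) and Dtx4 (-0.93). Angptl4 fell in both genotypes, with changes of -2.59 in WT and -1.47 in KO (adjusted p = 0.00669). Of the 26 lists 9 passed the list test for the interaction, without a called member in any. Without conditioned KO library 0 the interaction called 1419 genes, and without both KO libraries of number 0 it called 2605.

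Genes near F2rl1 can carry DNA of another strain along with a knockout. Within 10 Mb of F2rl1, 0 of 86 genes were called in either medium. An unadjusted p under 0.05 was found for 8 of these (9.30%) in unconditioned medium, against 2.12% of the other genes (Fisher's exact test, two-sided, p = 0.000533), and for 10 (11.6%) against 13.96% in conditioned medium (p = 0.640). By the same exact test with windows of 5 and 20 Mb, the shares in unconditioned medium were 12.3% of 57 genes (p = 0.000215) and 6.21% of 145 genes (p = 0.00426). The test named in the written design compares called genes, and the comparison by unadjusted p is an addition to it. The exact test takes neighbouring genes as independent, which was not tested.

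The authors' deposited tables hold Cuffdiff tests of other features. In the authors' deposited table of transcripts, 272 of 20461 tested were significant between KO and WT in unconditioned medium (188 higher and 84 lower in KO). In conditioned medium 883 of 20105 tested were significant (548 and 335). Between the media 1162 transcripts were significant in WT (609 higher and 553 lower in conditioned medium) and 2209 in KO (987 and 1222). In the same order, 362, 1165, 1442 and 2736 groups of transcripts with a shared start site were significant, and 282, 943, 1155 and 2182 coding sequences. Differential splicing was significant in 54, 26, 52 and 21 cases, promoter use in 24, 17, 37 and 17, and coding output in 16, 9, 19 and 9. These last counts were higher where the unconditioned WT group took part (splicing 54 and 52, against 26 and 21). The counts of transcripts, their groups and coding sequences did not divide this way. In the authors' table of fragments the unconditioned WT group holds a repeated library, so its replicates there are not all distinct. Whether the repeat entered these tests and changed their counts was not tested. Differences between the counts are therefore not interpreted.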

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

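The tests of the position of the KO libraries of number 0, of mixed groups of cultures and of their depth, and the fits without both of these libraries, were chosen only after the result was seen.

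In 9 of the 26 lists the effect of the medium differed between the libraries labelled KO and WT by a test of the difference itself (interaction, camera at the preset correlation), with 0 members called and an adjusted p of 0.824 for each with an estimated correlation and of 0.839 by fry. Interferon-stimulated genes had a median interaction of 1.11 (adjusted p = 3.82e-08, 31 of 34 positive), with Ifit1 at 2.82 (SE 1.10) and Oasl1 at 2.54 (SE 1.02). Genes of glycolysis and hypoxia had -0.62 (adjusted p = 1.51e-06, 34 of 39 negative), with P4ha1 at -0.62, and oxidative stress genes -0.55 (adjusted p = 1.51e-06, 24 of 28 negative), with Slc7a11 at -1.01 (SE 0.36). Smooth muscle genes had -0.55 (adjusted p = 0.00146, 17 of 18 negative), with the contractile Myl9 at -1.04 and Mylk at -1.36. Cholesterol synthesis genes had -0.63 (adjusted p = 4.10e-05, 24 of 25 negative), with Acat2 at -1.02, and this call was lost without conditioned WT library 1 (0.241). ER chaperones had -0.21 (adjusted p = 0.00444, 18 of 21 negative), a call lost without the same library (0.243). On the centred log2 scale conditioned KO library 0 stood apart from KO libraries 1 and 2 for glycolysis (0.21 against -0.67 and -0.92), oxidative stress (0.17 against -0.36 and -0.57) and smooth muscle genes (0.30 against -1.09 and -1.40). By the values given above, this library also lay below KO libraries 1 and 2 for interferon genes, and above them for cartilage genes. For interferon genes it lay below conditioned WT libraries 0 and 1 as well.

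Cartilage genes had a median interaction of -0.74 (adjusted p = 0.0173, 13 of 17 negative), with Col9a1 at -1.47, and were not called without unconditioned KO library 2 (0.104), unconditioned WT library 0 (0.157) or conditioned WT library 0 (0.262). BMP and TGF-beta targets had -0.34 (adjusted p = 0.0192, 26 of 33 negative; 0.32 in conditioned KO library 0 against -0.64 and -0.99 in libraries 1 and 2), not called without unconditioned KO library 0 (0.228), conditioned KO library 1 (0.0705), conditioned KO library 2 (0.230) or unconditioned WT library 0 (0.134). The PAR and coagulation list had -0.36 (adjusted p = 0.0397, 16 of 18 negative; 0.12 in conditioned KO library 0 against -0.62 and -0.78 in libraries 1 and 2), not called without unconditioned KO library 0 (0.228), conditioned KO library 1 (0.0669), conditioned KO library 2 (0.239), unconditioned WT library 0 (0.102) or conditioned WT library 2 (0.145).

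Between KO and WT in conditioned medium 0 genes were called, and 5765 without both KO libraries of number 0. Against low depth stands the total of 16.557 M fragments (16556983) in the conditioned library, near the top of the range of 15023994 to 16956754. Whether these libraries come from wild-type cells is left open: of 622 genes called at over 2-fold between KO libraries 1 and 2 and WT, KO library 0 lay nearer to KO for 2.57%, but these genes were chosen without it, so the pattern itself leads to a low share. With WT library 2 held out of the choice as well, the share of 423 genes was 12.3% for KO library 0 and 18.4% for WT library 2. Pisd-ps3, the single gene called in unconditioned medium, went the other way. It had 26.8 ± 2.30 CPM in KO and 59.1 ± 4.75 in WT there, and 40.9 ± 2.98 and 72.7 ± 5.44 CPM in conditioned medium. With SDs this small, KO library 0 lay with KO for this gene in both media. As 1 gene chosen with library 0 counted as KO, it does not settle the question. Differences between cultures whatever their genotype could also give the pattern, since conditioned KO library 0 with WT libraries 0 and 2 differed from KO libraries 1 and 2 with WT library 1 in 2076 genes, and an effect of the genotype that shows in KO libraries 1 and 2 stays open too.

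For KO against WT in conditioned medium, the 10 splits of the 6 libraries are too few for a share under 0.05; the real split called 0 genes and the highest other 2076. A split that calls this many genes points to a structure of the samples. For the medium in KO, 10 splits are again too few; the real split called 2484 genes and the highest other 0, so 1 split of 10 gave as many.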

How the results depend on the processing

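The tests chosen only after the result was seen are those with the repeated library counted as 2 or taken as number 1 in the block, with the batch term, and without both KO libraries 0 or without conditioned KO libraries 1 and 2. Over 134 results of genes, 2349 values kept their direction and side of the threshold, 316 fell below it, 102 passed it and 27 changed direction; over 50 results of lists these were 447, 121, 11 and 8. All 20 named genes of the medium in WT and all 20 in KO kept their direction everywhere; in the fits without 1 library, 0 of the 20 in WT and 10 of the 20 in KO kept their call in each. Scaling, filters and unrounded counts changed no count of calls by over 1.5 times. Where a cause is not given below, the cause was not tested. Fewer libraries lower the power of the fits that leave some out, and a group left with 1 library is assumed to vary like the others. At this depth F2rl1, with 12 to 46 fragments per library, is measured coarsely.

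For the medium in WT 242 genes were called. There were 923 with the repeated library counted as 2 (242 shared), 521 with the batch term and 363 in the fit of only 2 groups (165 shared). There were 155 with the replicate block (71 shared), 0 with the repeated library as number 1, 1589 without both KO libraries 0, 542 without conditioned KO libraries 1 and 2, 897 in DESeq2 (241 shared), and 0 to 444 without single libraries. Of the 242, 69.0% were higher, against 50.3% in DESeq2 and 45.2% with the replicate block. The fits without KO libraries left out no library of this comparison. Its count could change there only through what the 4 groups share: the estimated spread, the scaling and the choice of genes. The 242 calls thus depend on the KO libraries too. For KO against WT in unconditioned medium the 1 call became 0 with either block, in the fit of only 2 groups, in limma and without conditioned KO libraries 1 and 2, 659 without both KO libraries 0, and 0 to 2 without single libraries. For the medium in KO the 2484 calls became 534 in the fit of only 2 groups, 6822 without both KO libraries 0, 2 without conditioned KO libraries 1 and 2, and 319 to 6094 without single libraries; 53.0% were higher, against 44.6% and 45.3% in limma and 46.4% and 46.5% with the blocks. For KO against WT in conditioned medium the 0 calls became 5765 without both KO libraries 0, 2 in DESeq2, and 0 to 4507 without single libraries. With the batch term they stayed 0, with 3122 genes at an unadjusted p under 0.05. The interaction's 0 calls became 2605 without both KO libraries 0, and 0 to 1419 without single libraries.

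F2rl1 passed the threshold for the medium in KO at -1.19 with the repeated library counted as 2 (adjusted p = 0.0489), -1.91 without both KO libraries 0 (0.00400), -1.20 in DESeq2 (0.0448) and -0.45 in limma with 1 added (0.0413); it ranged from -1.82 to -0.90 without single libraries. Between genotypes in conditioned medium F2rl1 was at 0.78 without conditioned KO libraries 1 and 2, and from -0.63 to 0.29 without single libraries; its interaction was 0.0411 without these 2. Without conditioned KO libraries 1 and 2, Il6 was at -0.0753 between genotypes, -1.49 for the medium in KO and -1.12 for the interaction. In the same fit the medium in KO gave 0.37 for Nfatc1, -1.05 for Mcm2, -1.12 for Tyms, -0.30 for Ndrg1, -0.21 for Dnajb9 and -0.57 for Hspa5. Tyms was at -0.11 and -0.12 in limma with 1 and 0.1 added. Without single libraries, the medium in KO gave -0.19 to 0.47 for Tyms, -0.47 to 0.0872 for Nfatc1, -0.75 to 0.000849 for Psmb8 and -0.15 to 0.51 for Hspa5. In WT it gave -0.18 to 0.0530 for Nfatc1, -2.79 to 0.0739 for Ckm and -3.37 to 0.998 for Myh3, and Nfatc1 was at 0.0546 with the replicate block.

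Without single libraries, the adjusted p of lists that turned direction ranged as follows. For KO against WT in unconditioned medium it was 0.707 to 0.955 for osteoblast, 1.92e-32 to 0.0885 for skeletal muscle and 1.08e-10 to 0.370 for keratinocyte genes. In conditioned medium it was 0.204 to 0.974 for osteoblast and 2.68e-13 to 0.545 for cell cycle genes, and for the medium in WT 4.03e-12 to 0.487 for skeletal muscle. The interaction of the adipogenesis list turned with the replicate block (0.833).

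With the replicate block, the medium in KO gave 2213 calls (1800 with the repeated library as number 1), and calls of named genes changed only for Bglap2, F3, Pdpn, Iyd and Apln. For KO against WT in unconditioned medium Pisd-ps3 was not called (0.333 and 0.324), nor were keratinocyte genes (0.0625 and 0.0609), and adipogenesis genes were (0.0350). In WT cholesterol (0.456), glycolysis (0.879) and immediate early genes (0.139) were not called, and adipogenesis genes were with the repeated library as number 1 (0.00553). In the interaction cholesterol and ER chaperone genes (0.458 each) and, as number 1, cartilage genes (0.308) were not called.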

Other observations

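The tests for macrophages and for the number of WT libraries were chosen only after the result was seen, and the lysosomal, glucocorticoid and muscle gene sets were written down after the leading genes of the medium response had been seen, and the members named were chosen after their values were seen. Unlike those of the 26 lists, the p-values of these sets as a whole are not adjusted. The sets were not run with a block or without single libraries. With the repeated library as number 1, the block called 0 genes for the medium in WT.

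Lysosomal genes were higher as a set in conditioned medium. Of 54 such genes outside the 26 lists, 18 rose in WT, or 46 adjusted over the list alone (median log2 0.79, camera p = 0.00175 with an estimated correlation), and in KO 32 rose and 2 fell, or 40 and 2 over the list alone (median 0.65, p = 0.00914). Lamp1, a protein of the lysosomal membrane, rose by 1.15 in WT (adjusted p = 0.0260) and by 1.29 in KO (adjusted p = 0.00451). The lysosomal calcium channel Mcoln1 was at 1.27 in WT (adjusted p = 0.0592) and 1.75 in KO. With the 2 genes that the lists also hold, 56 genes gave medians of 0.77 and 0.63. A candidate explanation is that the medium raised a lysosomal programme to which Gpnmb, Rragd and Atp6v0d2 belong. A higher share of macrophages, each with as much Gpnmb as before, would have to raise their abundant genes in proportion to Gpnmb. Gpnmb rose by 3.03 in WT, but the 75th percentile of macrophage and leukocyte markers was 0.81 in WT and 0.70 in KO. A rise of Gpnmb within each macrophage was not tested. Cd68, an abundant gene of macrophages, had 3.55 to 13.9 CPM per library, and Ctss 4.21 to 11.7 CPM. A higher share of osteoclasts, whose own list was higher in both genotypes (medians 0.63 and 0.36), stays open.

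Genes that glucocorticoids induce were lower as a set, as were Fkbp5, Serpina3n and Angptl4. Of 19 such genes outside the 26 lists, 2 fell in WT, or 6 over the list alone (median -0.93, p = 0.0117 with an estimated correlation), and 8 in KO, or 13 lower and 1 higher over the list alone (median -1.04, p = 0.0226). Tsc22d3, an anti-inflammatory mediator of these hormones, was at -1.26 in WT (adjusted p = 0.0289) and -1.50 in KO (adjusted p = 0.00482), and Pdk4, which restrains glucose oxidation, at -1.45 and -1.84 (adjusted p = 0.0292 and 0.00450). Zbtb16 was at -3.39 in WT (adjusted p = 0.0596) and -3.02 in KO (adjusted p = 0.0232). With the genes that the lists also hold, 28 genes gave medians of -0.68 and -0.94. A candidate explanation is a weaker glucocorticoid signal in the conditioned medium, of which no hormone level was measured here. These sets were run first with all their members and then without the shared ones, and both runs gave the same direction.

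Skeletal muscle genes were high in unconditioned WT library 0 and conditioned WT library 1, the conditioned library with which library 0 correlated best in the check of pairs (0.466). Over 27 further muscle genes the centred medians were 1.90 and 1.61 in these libraries and at most 0.27 in the others, so 1 wild-type culture may have held muscle cells. Myog, a regulator of muscle formation, had 8.87 and 6.62 CPM there and 0.596 to 3.59 CPM elsewhere, and the giant muscle protein Ttn 26.4 and 35.3 CPM against 4.04 to 9.37. No explanation by genotype or medium was tested.

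More genes were called for the medium in KO (2484) than in WT (242), and no interaction was called. In fits of only the 2 groups compared, the counts were 534 in KO and 363 in WT. The size of the gap thus depends on what the 4 groups share in the main fit. Leaving out 1 unconditioned KO library gives KO as few libraries as WT. This lowered the count in KO to 400 without library 1 and to 457 without library 2, but raised it to 3101 without library 0, so whether the number of libraries may account for part of the difference stays open.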
